A study of Mus musculus with 20 samples.

How the data were processed

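Total RNA of the middle colon from 20 female C57BL/6JOlaHsd mice, 1 array per mouse, was labelled with biotin and hybridised to Affymetrix arrays. The 5 groups of 4 mice were untreated (saline) healthy, probiotic healthy, untreated colitis, probiotic colitis and cyclosporine colitis, each array taking its group and animal number from its title. The series states biological replicates, so the arrays are separate mice. The values are log2 expression per probe set as deposited by the authors, normalised with RMA according to the submitters' processing notes, whose version and annotation are not given in the sources used here. Values were used as deposited, with no further normalization. Of 41801 probe sets, 29195 had a value on every array and 12606 on none, and every column of per-sample values was used. The table of probe set genes gave 1 symbol for 22360 probe sets with values, several for 1013 and none for 5822, which were tested apart. Of the tested genes 16660 were found by gene identifier in the RefSeq table of the assembly GRCm38.p6, with 0 symbols differing, and that table was used for names alone.

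Genes were tested in R 4.3.3 with limma 3.58.1. A probe set was kept if its value exceeded 5.30, the 25th percentile of all values of named probe sets, on at least 4 of the 20 arrays, and the probe set with the highest mean stood for its gene where there were several (607 genes). This left 16739 of 21423 gene symbols, 4684 being left out as dim. Signal over background sets what arrays can show, and 15 of the 85 genes named for size of change had a group mean under the filter level, so that their changes are compressed by background. Group means were fitted with lmFit over all 20 arrays and moderated with eBayes (15 residual and 4.03 prior degrees of freedom), and 8 comparisons were read from the fit with a Benjamini-Hochberg adjusted p under 0.05 in each. Animal numbers name mice within a group, so no pairs were formed. The labels give 5 mice per cage without the cage of each mouse, so a shared cage of a group was not analysed here.

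The design, 29 gene lists, the rule for named genes and the main alternatives were fixed before the data were examined. The named genes of a comparison were the 12 with the largest and the 12 with the smallest log2 change among those that pass and whose groups of 4 arrays do not overlap, or the 3 with the smallest p in a direction where none pass. Up to 4 members with the smallest p could be named per list, and predicted genes, noncoding series and receptor segments were not named one by one. The lists cover cell types of the colon and blood, and inflammatory, epithelial, metabolic, position, handling and reference genes. The 28 lists with at least 5 tested members were tested with camera at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with a correlation estimated for each list and with fry, which tests whether the members move one way on balance and does not compare them with other genes. No called list had a median, mean and test of different sign. Scores were compared with exact two-sided permutation tests over the 70 assignments of 4 against 4, among colitis groups or among healthy groups alone, because the genes of the score were chosen for the difference between colitis and healthy. Of these 4 tests, the 2 against untreated colitis were in the design.

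The fit was tested on simulated data for 16739 genes, with 67, 67 and 66 genes changed by 0.5, 1 and 2 on the log2 scale. With the spread of each group, the comparisons of colitis, probiotic against untreated colitis, cyclosporine against untreated colitis and probiotic against untreated healthy recovered 79.1% to 86.6%, 97.0% to 98.5% and 98.5% to 100% of these. False calls were then 15.8%, 15.2%, 18.6% and 6.63% of all calls in the same order, above the nominal 5%, and with a spread shared by the groups they were 2.03%, 3.08%, 4.04% and 3.96%. So false calls can exceed the nominal 5% where groups differ in spread. Few genes were changed, so these shares do not carry over to real calls. Of 28 lists, 1 shifted by 0.5 was called and 0 others were, in probiotic against untreated colitis. Simulated genes were independent, so the preset correlation of the list test was not checked. Alternatives tried were no filter, a stricter filter (50th percentile, 6.60), quantile normalization again, arrays centred on their median, eBayes with trend and robust, array weights, a mean of probe sets, animal number as a block, a fit of the compared groups alone and leaving out each array. For the score, genes with no minimum fold and fixed lists in place of chosen genes were tried, and for correlations the split of shared arrays, score genes alone and no filter. Alternatives added after seeing the data are named below. The median change over all genes stayed within 0.1 of 0 under both scalings. No genome coordinates were used here.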

Results

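Gene expression was measured on 20 arrays of the middle colon, 1 per mouse, in 5 groups of 4 female C57BL/6JOlaHsd mice about 11 weeks old. Of the 5 groups, 2 were healthy, one given saline and one a probiotic mixture of the strains L930BB and IM386. The other 3 groups drank 3% dextran sulphate sodium (DSS), a polymer that injures the colonic epithelium, for 5 days, and received saline, the probiotic mixture by gavage, or cyclosporine A, a calcineurin inhibitor that blocks T cell activation, at 25 mg/kg by mouth daily from day 1 to day 15. The saline groups are called untreated, and no healthy group received cyclosporine. Arrays carry no read depth, and the number of arrays limits the precision. Array medians lay between 6.22 and 6.29 on the log2 scale, the correlation of array pairs between 0.965 and 0.994, and no arrays were identical. The first principal component held 55.9% of the variance and followed colitis, while components 2 and 3 held 7.52% and 6.89%. Untreated healthy mouse 2, untreated colitis mouse 6 and probiotic colitis mouse 8 stood apart from the other arrays of their groups on these components. Changes are given as log2 change ± standard error of the fit, n = 4 mice per group, and genes named for their size had no overlap between the 4 arrays of one group and the 4 of the other.

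In untreated colitis, genes of innate inflammation and epithelial defence rose and genes of colonocyte transport and metabolism fell. This comparison with untreated healthy mice asks what DSS injury does to the middle colon. The largest rises were those of Clca4b, an epithelial chloride channel accessory gene, by 6.88 ± 0.73 (117-fold), and of Plet1, a surface gene of epithelial progenitors, by 4.82 ± 0.35 (28.2-fold). The acute phase gene Saa3 (3.95 ± 0.97), the interleukin gene Il1b (3.51 ± 0.71) and the nitric oxide synthase gene Nos2 (3.44 ± 0.43) rose. So did the goblet cell gene Retnlb (3.36 ± 0.41), the neutrophil surface gene Cd177 (2.86 ± 0.21) and the metalloreductase gene Steap4 (2.85 ± 0.19). The largest falls were those of the mucosal pentraxin Mptx1 (-4.20 ± 0.52), the sugar phosphate transporter Slc37a2 (-3.22 ± 0.33) and the cytochrome P450 gene Cyp2c69 (-2.87 ± 0.51). The ion transport regulator Fxyd4 (-2.14 ± 0.29), the phosphate transporter Slc20a1 (-1.93 ± 0.23) and the urea cycle gene Otc (-1.97 ± 0.30) fell too. In all, 1957 genes rose and 2404 fell of 16739 tested, 322 and 135 of them by at least 2-fold.

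Immune cell and cytokine lists rose in untreated colitis. Of 28 lists 24 were called, 16 up and 8 down. Acute inflammatory cytokines and chemokines rose as a list (median 1.13, adjusted p = 2.04e-06, adjusted p = 0.186 with an estimated correlation). The median was 0.70 without untreated colitis mouse 7. Tnf (1.51 ± 0.24), Il1b (3.51 ± 0.71) and Cxcl5 (2.02 ± 0.47) were among the 9 of 15 members that rose, 6 not passing and 14 up adjusted over the list alone. Neutrophil markers rose as a list (median 1.43, adjusted p = 7.82e-05, adjusted p = 0.318 with an estimated correlation). The median was 0.94 without untreated colitis mouse 7. Of 16 members 9 rose, 7 not passing and 11 up adjusted over the list alone. S100a9 (2.43 ± 0.66) rose. Macrophage markers rose as a list (median 0.55, adjusted p = 6.48e-07, adjusted p = 0.186 with an estimated correlation). Mpeg1 (1.35 ± 0.19), Ccr2 (1.28 ± 0.26) and Lyz2 (1.01 ± 0.22) were among the 11 of 17 members that rose, 6 not passing and 13 up adjusted over the list alone. T cell markers rose as a list (median 0.56, adjusted p = 2.04e-06, adjusted p = 0.186 with an estimated correlation). The median was 0.31 without untreated colitis mouse 5. Cd3g (1.83 ± 0.27), Cd5 (0.55 ± 0.11) and Cd4 (0.98 ± 0.23) were among the 9 of 13 members that rose, 4 not passing and 12 up adjusted over the list alone. Targets of T cell activation and calcineurin-NFAT signalling rose as a list (median 0.18, adjusted p = 0.00958, adjusted p = 0.321 with an estimated correlation). The median was 0.10 without untreated colitis mouse 5. Icos (1.02 ± 0.18), Ctla4 (0.85 ± 0.18) and Il2ra (0.87 ± 0.18) were among the 5 of 13 members that rose, 8 not passing and 5 up adjusted over the list alone. B cell and plasma cell markers rose as a list (median 1.31, adjusted p = 2.50e-07, adjusted p = 0.186 with an estimated correlation). Cxcl13 (1.99 ± 0.33), Cr2 (2.54 ± 0.45) and Mzb1 (1.35 ± 0.25) were among the 12 of 15 members that rose, 3 not passing and 13 up adjusted over the list alone.

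Interferon genes and epithelial defence genes rose in the same comparison. Interferon gamma and MHC class II genes rose as a list (median 1.10, adjusted p = 8.77e-12, adjusted p = 0.186 with an estimated correlation). Psmb8 (0.98 ± 0.17), Psmb9 (0.92 ± 0.16) and Gbp3 (1.33 ± 0.23) were among the 16 of 17 members that rose, 1 not passing and 17 up adjusted over the list alone. Type I interferon genes rose as a list (median 0.65, adjusted p = 2.31e-07, adjusted p = 0.186 with an estimated correlation). Oas2 (1.54 ± 0.28), Ifit2 (0.86 ± 0.17) and Oasl2 (1.38 ± 0.31) were among the 10 of 18 members that rose, 8 not passing and 12 up adjusted over the list alone. Epithelial antimicrobial and acute phase genes rose as a list (median 1.14, adjusted p = 1.13e-07, adjusted p = 0.0313 with an estimated correlation). Duox2 (1.69 ± 0.15), Slpi (2.36 ± 0.27) and Dmbt1 (0.73 ± 0.09) were among the 11 of 16 members that rose, 5 not passing and 12 up adjusted over the list alone. This was the only list called with an estimated correlation in any of the 8 comparisons. Toll-like receptor and NF-kB genes rose as a list (median 0.24, adjusted p = 0.000812, adjusted p = 0.186 with an estimated correlation). Of 23 members 11 rose and 1 fell, 11 not passing and 11 up and 1 down adjusted over the list alone. Nfkbiz (0.96 ± 0.17) and Tlr2 (0.83 ± 0.15) rose while Tlr5 (-0.60 ± 0.09) fell. Chaperones of the unfolded protein response rose as a list (median 0.36, adjusted p = 3.33e-07, adjusted p = 0.166 with an estimated correlation). Hsp90b1 (0.55 ± 0.07), Dnajc3 (0.50 ± 0.06) and Creld2 (0.69 ± 0.11) were among the 10 of 15 members that rose, 5 not passing and 11 up adjusted over the list alone. Goblet cell markers rose as a list (median 0.11, adjusted p = 0.00493, adjusted p = 0.351 with an estimated correlation). The median was 0.06 to 0.29 without untreated healthy mouse 6 or 7 or untreated colitis mouse 5, 7 or 10. Galnt12 (0.89 ± 0.11), Spink4 (1.34 ± 0.19) and Muc2 (0.32 ± 0.07) were among the 6 of 15 members that rose, 9 not passing and 6 up adjusted over the list alone.

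Absorptive and metabolic genes fell in untreated colitis. Colonocyte markers fell as a list (median -0.36, adjusted p = 0.000811, adjusted p = 0.186 with an estimated correlation). The median was -0.60 without untreated healthy mouse 6 and -0.56 without untreated colitis mouse 7. Of 18 members 1 rose and 7 fell, 10 not passing and 1 up and 8 down adjusted over the list alone. Car1 (-1.26 ± 0.12), Aqp8 (-1.56 ± 0.20) and Car2 (-0.92 ± 0.12) fell. These are carbonic anhydrase and water channel genes of the surface epithelium. Xenobiotic metabolism and drug transport genes fell as a list (median -0.54, adjusted p = 1.16e-06, adjusted p = 0.148 with an estimated correlation). Of 19 members 2 rose and 13 fell, 4 not passing and 2 up and 13 down adjusted over the list alone. Gstt1 (-0.98 ± 0.08), Gstm1 (-1.22 ± 0.12) and Sult1a1 (-1.83 ± 0.23) fell. Fatty acid oxidation genes and PPAR targets fell as a list (median -0.39, adjusted p = 5.14e-05, adjusted p = 0.186 with an estimated correlation). Acadvl (-0.51 ± 0.06), Ech1 (-0.44 ± 0.08) and Acaa2 (-0.59 ± 0.11) were among the 12 of 16 members that fell, 4 not passing and 12 down adjusted over the list alone. Tight junction and barrier genes fell as a list (median -0.19, adjusted p = 0.0148, adjusted p = 0.354 with an estimated correlation), a call lost without untreated colitis mouse 5 (adjusted p = 0.123). Of 21 members 1 rose and 8 fell, 12 not passing and 1 up and 9 down adjusted over the list alone. Cell cycle genes rose as a list (median 0.27, adjusted p = 0.0111, adjusted p = 0.447 with an estimated correlation), a call lost without untreated healthy mouse 6 (adjusted p = 0.168). The median was 0.08 without untreated healthy mouse 6. Of 19 members 4 rose, 15 not passing and 4 up adjusted over the list alone. Not called were stem cell and Wnt targets (median -0.31, adjusted p = 0.165) and enteroendocrine and tuft cell markers (median -0.15, adjusted p = 0.117) in camera, while fry called both down (adjusted p = 0.00591 and 0.00806). For stem cell and Wnt targets, of 14 members 4 rose and 7 fell, 3 not passing and 4 up and 9 down adjusted over the list alone. There Lgr5 (-1.13 ± 0.20) and Znrf3 (-0.46 ± 0.08) fell while Prom1 (1.29 ± 0.16) and Cd44 (0.93 ± 0.18) rose. For enteroendocrine and tuft cell markers, of 16 members 1 rose and 4 fell, 11 not passing and 1 up and 4 down adjusted over the list alone.

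Markers of other tissue layers differed between the same groups of arrays. Smooth muscle markers fell as a list (median -0.61, adjusted p = 4.69e-08, adjusted p = 0.186 with an estimated correlation). Casq2 (-1.14 ± 0.16), Pgm5 (-1.03 ± 0.18) and Kcnmb1 (-0.67 ± 0.12) were among the 13 of 14 members that fell, 1 not passing and 14 down adjusted over the list alone. Enteric neuron and glia markers fell as a list (median -0.31, adjusted p = 0.00665, adjusted p = 0.297 with an estimated correlation). Of 14 members 2 rose and 6 fell, 6 not passing and 2 up and 10 down adjusted over the list alone. Snap25 (-0.90 ± 0.13) and Stmn2 (-0.66 ± 0.10) fell. Posterior Hox genes, which mark position along the gut, fell as a list (median -0.68, adjusted p = 0.000585, adjusted p = 0.186 with an estimated correlation). Hoxb13 (-0.60 ± 0.10), Hoxd11 (-1.43 ± 0.27) and Hoxd12 (-0.92 ± 0.18) were among the 5 of 8 members that fell, 3 not passing and 5 down adjusted over the list alone. Extracellular matrix and wound repair genes rose as a list (median 0.61, adjusted p = 6.48e-07, adjusted p = 0.186 with an estimated correlation). Of 17 members 13 rose and 1 fell, 3 not passing and 13 up and 1 down adjusted over the list alone. Lox (1.66 ± 0.29), Col4a1 (0.72 ± 0.13) and Col1a2 (0.52 ± 0.12) rose. Adipocyte markers fell as a list (median -0.35, adjusted p = 0.0471, adjusted p = 0.447 with an estimated correlation), a call lost without untreated healthy mouse 2 or 7 or untreated colitis mouse 6 or 10 (adjusted p = 0.0602 to 0.120). Of 10 members 3 fell, 7 not passing and 3 down adjusted over the list alone. Mast cell and eosinophil markers rose as a list (median 0.17, adjusted p = 0.0495, adjusted p = 0.249 with an estimated correlation), a call lost without untreated healthy mouse 2, 6 or 7 or untreated colitis mouse 6 or 10 (adjusted p = 0.0541 to 0.0912). Of 8 members 2 rose and 1 fell, 5 not passing and 3 up and 1 down adjusted over the list alone. Also not called were endothelial markers (median 0.13, adjusted p = 0.0569). They were called up without untreated healthy mouse 4, 6 or 7 or untreated colitis mouse 6 or 10 (median 0.14 to 0.28, adjusted p = 0.000515 to 0.0452). Of the erythroid markers 2 were tested, too few for a list test.

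**Figure D1:**
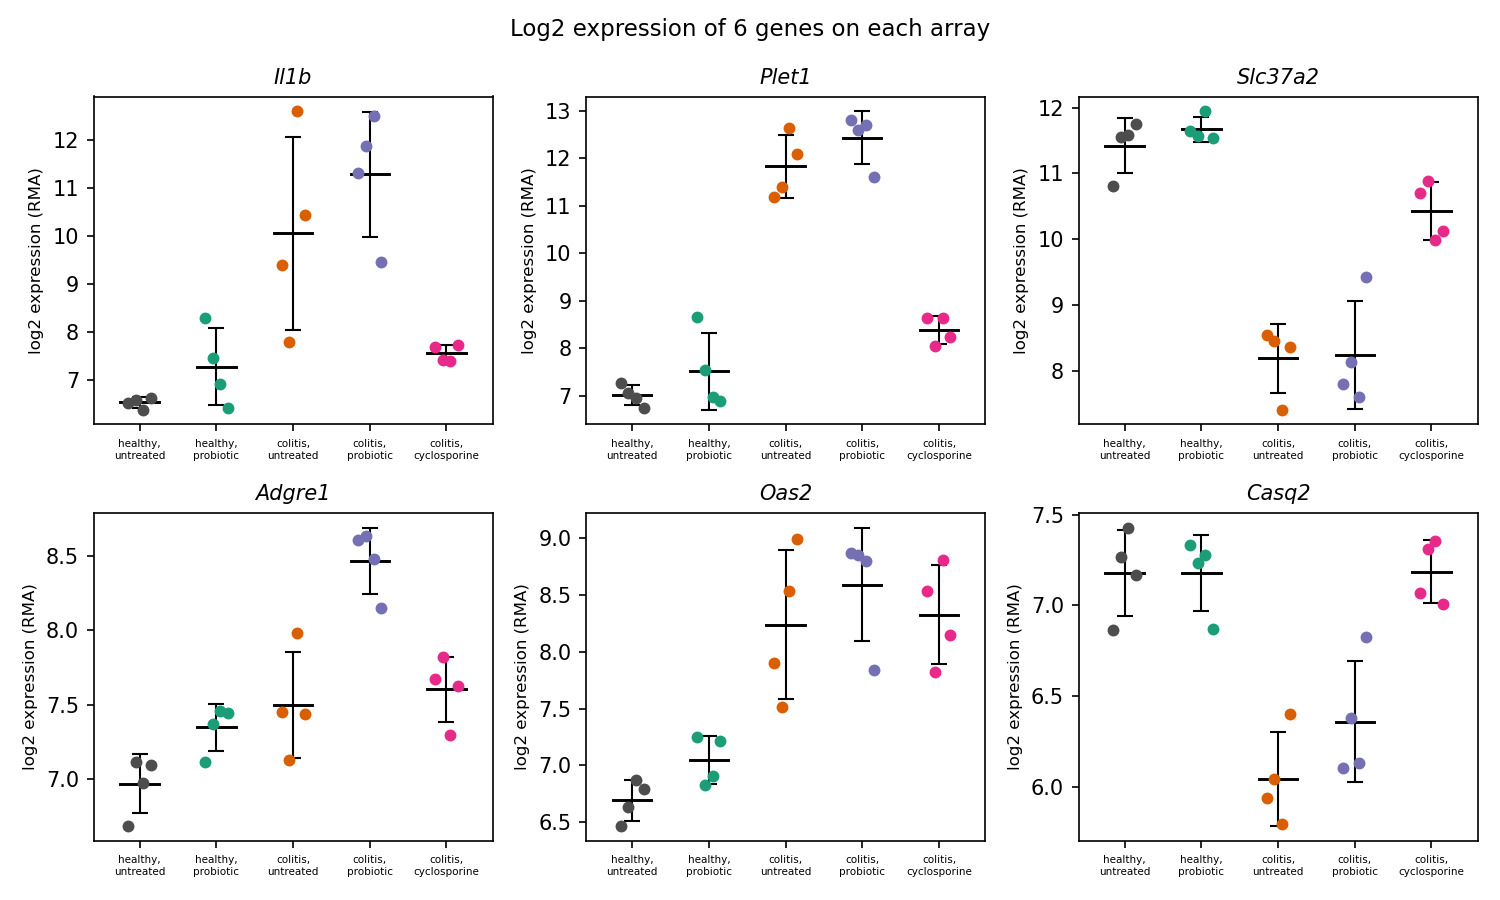
Log2 expression of Il1b, Plet1, Slc37a2, Adgre1, Oas2 and Casq2 on each of 20 arrays (points) with group mean and SD (bars, n = 4) in the 5 groups. Mean Il1b was 6.54 in untreated healthy, 10.06 in untreated colitis, 11.28 in probiotic colitis and 7.57 in cyclosporine colitis.

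In healthy mice vascular markers moved as a list under the probiotic, while no single gene passed. This comparison asks what the mixture does without colitis. In limma 0 genes passed, with 1511 of 16739 at an unadjusted p under 0.05 and a smallest adjusted p of 0.206. The smallest p upward were those of the signalling adaptor Traf4 (0.43 ± 0.08, adjusted p = 0.206) and the steroid synthesis gene Cyp11a1 (0.68 ± 0.13, adjusted p = 0.206). Downward they were those of Tmem256 (-0.44 ± 0.08, adjusted p = 0.206) and the mitochondrial gene Hint2 (-0.43 ± 0.08, adjusted p = 0.206). Endothelial markers rose as a list (median 0.36, adjusted p = 9.13e-12, adjusted p = 0.603 with an estimated correlation). Of 14 members 0 passed over all genes and 9 up adjusted over the list alone. The smallest p of its members were those of the angiopoietin receptor Tek (0.56 ± 0.14, adjusted p = 0.301) and the vascular phosphatase Ptprb (0.57 ± 0.14, adjusted p = 0.301). The endothelial mean of untreated healthy mouse 2 was 7.21, below the 7.46 to 7.49 of the other 3 mice. Without the 3 arrays that stand apart the endothelial median was 0.30. A fit of these 8 arrays alone called 19 genes.

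Of the other 27 lists, 5 were called in healthy mice given the probiotic. In each of the 5, 0 members passed over all genes and 0 adjusted over the list alone. Macrophage markers rose as a list (median 0.27, adjusted p = 0.00143, adjusted p = 0.929 with an estimated correlation). Interferon gamma and MHC class II genes rose as a list (median 0.22, adjusted p = 0.0209, adjusted p = 0.929 with an estimated correlation), a call lost without untreated healthy mouse 6 or probiotic healthy mouse 4 or 7 (adjusted p = 0.0528 to 0.0825). Matrix and wound repair genes rose as a list (median 0.15, adjusted p = 0.0291, adjusted p = 0.929 with an estimated correlation), a call lost without untreated healthy mouse 2 or 7 or probiotic healthy mouse 4, 5 or 7 (adjusted p = 0.0528 to 0.135). Adipocyte markers rose as a list (median 0.32, adjusted p = 0.0209, adjusted p = 0.929 with an estimated correlation), a call lost without untreated healthy mouse 4 or 6 or probiotic healthy mouse 4 (adjusted p = 0.0652 to 0.313). The median was 0.19 without probiotic healthy mouse 4. Colonocyte markers fell as a list (median -0.10, adjusted p = 0.0209, adjusted p = 0.929 with an estimated correlation), a call lost without untreated healthy mouse 2 or probiotic healthy mouse 5 (adjusted p = 0.0548 to 0.141). The median was -0.14 without untreated healthy mouse 6 and -0.15 without probiotic healthy mouse 6. Without probiotic healthy mouse 4, 3 lists were called in place of 6.

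Macrophage genes were higher in probiotic colitis than in untreated colitis. This comparison asks whether the probiotic mixture changes the response to DSS. The phagocyte receptors Clec7a (1.67 ± 0.29) and Clec12a (1.65 ± 0.22), the complement gene C1qb (1.29 ± 0.22) and the macrophage surface gene Adgre1 (0.97 ± 0.16) rose. The complement receptor C3ar1 (0.96 ± 0.16), the nuclease gene Dnase1l3 (1.08 ± 0.18) and the lymphocyte receptor Slamf7 (1.14 ± 0.20) rose too. The T cell gene Cd4 (1.08 ± 0.23) rose, a call lost without untreated colitis mouse 6 or 10 or probiotic colitis mouse 5 or 7 (adjusted p = 0.0553 to 0.0973). The largest falls were those of the colonic cytochrome P450 gene Cyp2c55 (-2.39 ± 0.46) and the sphingolipid gene Sptssb (-1.48 ± 0.29). The interleukin gene Il1b had a value of 1.23 ± 0.71 (adjusted p = 0.388).

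For the probiotic in colitis 356 genes rose and 112 fell, 32 and 6 of them by at least 2-fold. Of the called genes 76.1% rose, and 63.5% did after quantile normalization. Of 45 genes tested by leaving out each array in turn, 29 lost their call at least once, and the count of 468 genes depended on single arrays. It was 1156 without untreated colitis mouse 5, 83 without mouse 6 and 203 without mouse 10. It was 165 without probiotic colitis mouse 3, 71 without mouse 5, 111 without mouse 7 and 1223 without mouse 8. In a fit of these 8 arrays alone 0 genes passed in limma, with 2533 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0994. Array weights raised the count to 1682.

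Of 28 lists 14 were called for the probiotic in colitis, 10 up and 4 down. Macrophage markers rose as a list (median 0.87, adjusted p = 1.85e-17, adjusted p = 0.224 with an estimated correlation). Aif1 (0.81 ± 0.12), Adgre1 (0.97 ± 0.16) and Ms4a7 (0.71 ± 0.12) were among the 13 of 17 members that rose, 4 not passing and 15 up adjusted over the list alone. Interferon gamma and MHC class II genes rose as a list (median 0.74, adjusted p = 4.63e-12, adjusted p = 0.224 with an estimated correlation). Of 17 members 4 rose, 13 not passing and 15 up adjusted over the list alone. H2-Eb1 (0.87 ± 0.17) rose, a call lost without untreated colitis mouse 6 or probiotic colitis mouse 5 (adjusted p = 0.0531 to 0.0643). Endothelial markers rose as a list (median 0.50, adjusted p = 1.94e-11, adjusted p = 0.224 with an estimated correlation). Of 14 members 4 rose, 10 not passing and 13 up adjusted over the list alone. Kdr (0.45 ± 0.11) rose, a call lost without untreated colitis mouse 6 or 10 or probiotic colitis mouse 3, 5 or 7 (adjusted p = 0.0796 to 0.149). T cell markers rose as a list (median 0.26, adjusted p = 7.99e-06, adjusted p = 0.330 with an estimated correlation). The median was 0.55 without untreated colitis mouse 5 and 0.17 without mouse 6. Of 13 members 2 rose, 11 not passing and 4 up adjusted over the list alone. Cd28 (0.87 ± 0.14) rose. T cell activation targets rose as a list (median 0.35, adjusted p = 2.70e-05, adjusted p = 0.243 with an estimated correlation). The median was 0.23 without untreated colitis mouse 6 and 0.23 without probiotic colitis mouse 7. Of 13 members 2 rose, 11 not passing and 5 up adjusted over the list alone. Ctla4 (0.68 ± 0.18) rose, a call lost without untreated colitis mouse 6 or 7 or probiotic colitis mouse 3, 5 or 7 (adjusted p = 0.0575 to 0.126), the change being 0.44 without untreated colitis mouse 6. B cell and plasma cell markers rose as a list (median 0.57, adjusted p = 8.64e-05, adjusted p = 0.330 with an estimated correlation). The median was 0.90 without untreated colitis mouse 5 and 0.30 without mouse 6. Of 15 members 1 rose, 14 not passing and 3 up adjusted over the list alone. Derl3 (0.79 ± 0.18) rose, a call lost without untreated colitis mouse 6 or 10 or probiotic colitis mouse 3 or 7 (adjusted p = 0.0562 to 0.0881). Neutrophil markers rose as a list (median 0.67, adjusted p = 0.000676, adjusted p = 0.512 with an estimated correlation), a call lost without untreated colitis mouse 6 (adjusted p = 0.0771). The median was 0.33 to 1.33 without untreated colitis mouse 6 or 7 or probiotic colitis mouse 3, 7 or 8. Of 16 members 0 passed over all genes and 0 adjusted over the list alone. Toll-like receptor and NF-kB genes rose as a list (median 0.14, adjusted p = 0.000125, adjusted p = 0.224 with an estimated correlation). The median was 0.09 to 0.25 without untreated colitis mouse 7 or probiotic colitis mouse 5 or 8. Of 23 members 0 passed over all genes and 0 adjusted over the list alone.

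Matrix, handling and epithelial lists were the other called ones in probiotic colitis. Matrix and wound repair genes rose as a list (median 0.27, adjusted p = 0.000116, adjusted p = 0.419 with an estimated correlation), a call lost without untreated colitis mouse 6 (adjusted p = 0.0636). The median was 0.09 to 0.43 without untreated colitis mouse 6 or 7 or probiotic colitis mouse 8. Of 17 members 1 rose, 16 not passing and 4 up adjusted over the list alone. Immediate early and heat shock genes, which respond to tissue handling, rose as a list (median 0.34, adjusted p = 0.00713, adjusted p = 0.512 with an estimated correlation), a call lost without untreated colitis mouse 5 or probiotic colitis mouse 8 (adjusted p = 0.0501 to 0.314). The median was 0.52 without untreated colitis mouse 7 and 0.15 without probiotic colitis mouse 8. Of 16 members 0 passed over all genes and 0 adjusted over the list alone. Colonocyte markers fell as a list (median -0.39, adjusted p = 5.32e-05, adjusted p = 0.224 with an estimated correlation). Of 18 members 3 fell, 15 not passing and 7 down adjusted over the list alone. Cyp2c55 (-2.39 ± 0.46) fell. Goblet cell markers fell as a list (median -0.23, adjusted p = 0.000360, adjusted p = 0.419 with an estimated correlation). Of 15 members 0 passed over all genes and 4 down adjusted over the list alone. Fatty acid oxidation genes fell as a list (median -0.17, adjusted p = 0.000615, adjusted p = 0.330 with an estimated correlation). The median was -0.11 without untreated colitis mouse 6. Of 16 members 1 fell, 15 not passing and 1 down adjusted over the list alone. Enteroendocrine and tuft cell markers fell as a list (median -0.09, adjusted p = 0.0459, adjusted p = 0.330 with an estimated correlation), a call lost without untreated colitis mouse 5 or 7 or probiotic colitis mouse 3 or 5 (adjusted p = 0.0529 to 0.138). The median was -0.15 to -0.05 without untreated colitis mouse 7 or probiotic colitis mouse 5, 7 or 8. Of 16 members 2 fell, 14 not passing and 1 up and 4 down adjusted over the list alone. Not called were acute inflammatory cytokines (median 0.25, adjusted p = 0.0666), type I interferon genes (median 0.17, adjusted p = 0.0639) and epithelial antimicrobial genes (median 0.04, adjusted p = 0.735). The cytokines were called up without untreated colitis mouse 7 or probiotic colitis mouse 8 (median 0.77 to 0.83, adjusted p = 4.67e-07 to 0.000505). Type I interferon genes were called up without untreated colitis mouse 7 or 10 or probiotic colitis mouse 8 (median 0.25 to 0.35, adjusted p = 0.000117 to 0.0220).

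Genes changed in both directions under cyclosporine A. This comparison of cyclosporine colitis with untreated colitis asks what an immunosuppressant does in this model. The epithelial genes Plet1 (-3.44 ± 0.35) and Sptssb (-3.31 ± 0.29), the goblet cell gene Retnlb (-2.78 ± 0.41) and the acute phase gene Hp (-2.56 ± 0.50) fell. The nitric oxide synthase gene Nos2 (-2.60 ± 0.43), the metalloreductase gene Steap4 (-2.12 ± 0.19) and the intestinal homeobox gene Isx (-2.16 ± 0.24) fell too. Il1b (-2.49 ± 0.71) fell, a call lost without untreated colitis mouse 7 or 10 or cyclosporine mouse 4, 7 or 9 (adjusted p = 0.0505 to 0.0884), the change being -1.65 without untreated colitis mouse 7. Clca4b (-2.63 ± 0.73) fell, a call lost without untreated colitis mouse 7 or cyclosporine mouse 7 (adjusted p = 0.0522 to 0.0873). The pentraxin Mptx1 (3.33 ± 0.52), the cytochrome P450 gene Cyp2c69 (3.23 ± 0.51) and the transporter Slc37a2 (2.23 ± 0.33) rose. Altogether 1268 genes rose and 934 fell, 86 and 64 of them by at least 2-fold. Leaving out each array in turn, 32 of 97 genes tested lost their call. The count of 2202 was 1353 without cyclosporine mouse 7 and 1119 in a fit of these 8 arrays alone.

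Immune and stress lists fell under cyclosporine. Of 28 lists 17 were called, 5 up and 12 down. Acute inflammatory cytokines fell as a list (median -0.70, adjusted p = 4.91e-06, adjusted p = 0.331 with an estimated correlation). The median was -1.27 without untreated colitis mouse 6 and -0.39 without mouse 7. Tnf (-1.23 ± 0.24) and Cxcl5 (-1.93 ± 0.47) were among the 6 of 15 members that fell, 9 not passing and 11 down adjusted over the list alone. Neutrophil markers fell as a list (median -1.45, adjusted p = 5.83e-05, adjusted p = 0.395 with an estimated correlation). The median was -0.94 without untreated colitis mouse 7. Of 16 members 4 fell, 12 not passing and 12 down adjusted over the list alone. Epithelial antimicrobial genes fell as a list (median -0.67, adjusted p = 1.08e-05, adjusted p = 0.114 with an estimated correlation). Retnlb (-2.78 ± 0.41), Dmbt1 (-0.61 ± 0.09) and Slpi (-1.64 ± 0.27) were among the 7 of 16 members that fell, 9 not passing and 1 up and 12 down adjusted over the list alone. B cell and plasma cell markers fell as a list (median -0.80, adjusted p = 0.000141, adjusted p = 0.331 with an estimated correlation). The median was -0.48 without untreated colitis mouse 5. Of 15 members 3 fell, 12 not passing and 8 down adjusted over the list alone. Mzb1 (-0.94 ± 0.25) fell, a call lost without untreated colitis mouse 5 or 7 (adjusted p = 0.0524 to 0.0650). Interferon gamma and MHC class II genes fell as a list (median -0.59, adjusted p = 3.00e-05, adjusted p = 0.395 with an estimated correlation). Of 17 members 2 fell, 15 not passing and 2 down adjusted over the list alone. Psmb8 (-0.64 ± 0.17) fell. Chaperones of the unfolded protein response fell as a list (median -0.34, adjusted p = 6.14e-08, adjusted p = 0.154 with an estimated correlation). Sdf2l1 (-0.57 ± 0.10) and Calr (-0.37 ± 0.07) were among the 10 of 15 members that fell, 5 not passing and 12 down adjusted over the list alone. Toll-like receptor and NF-kB genes fell as a list (median -0.18, adjusted p = 0.00522, adjusted p = 0.331 with an estimated correlation). The median was -0.28 without untreated colitis mouse 6. Of 23 members 1 rose and 6 fell, 16 not passing and 1 up and 7 down adjusted over the list alone. Nfkb2 (-0.60 ± 0.14), Tnfaip3 (-0.47 ± 0.12) and Tlr2 (-0.62 ± 0.15) fell while Tlr5 (0.49 ± 0.09) rose. Not called were macrophage markers (median -0.17, adjusted p = 0.289) and type I interferon genes (median -0.11, adjusted p = 0.257). Macrophage markers were called down without untreated colitis mouse 6 (median -0.30, adjusted p = 0.0108). Type I interferon genes were called down without untreated colitis mouse 5 or 6 (median -0.20 to -0.17, adjusted p = 0.0456 to 0.0457). Among macrophage genes Ms4a7 (0.57 ± 0.12) rose.

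T cell lists, which cover the target of cyclosporine, fell with few members passing. T cell markers fell as a list (median -0.39, adjusted p = 0.00449, adjusted p = 0.522 with an estimated correlation), a call lost without untreated colitis mouse 5 (adjusted p = 0.255). The median was -0.13 without untreated colitis mouse 5. Of 13 members 1 fell, 12 not passing and 4 down adjusted over the list alone. Cd5 (-0.45 ± 0.11) fell. T cell activation and calcineurin-NFAT targets fell as a list (median -0.19, adjusted p = 0.0340, adjusted p = 0.522 with an estimated correlation), a call lost without untreated colitis mouse 5 or 7 or cyclosporine mouse 9 (adjusted p = 0.0733 to 0.198). The median was -0.08 without untreated colitis mouse 5 and -0.33 without mouse 6. Of 13 members 3 fell, 10 not passing and 4 down adjusted over the list alone. Il2ra (-0.66 ± 0.18) fell, a call lost without untreated colitis mouse 5, 7 or 10 or cyclosporine mouse 7 or 9 (adjusted p = 0.0586 to 0.0741). Goblet cell markers fell as a list (median -0.11, adjusted p = 0.0340, adjusted p = 0.596 with an estimated correlation), a call lost without untreated colitis mouse 6, 7 or 10 or cyclosporine mouse 7 or 10 (adjusted p = 0.0630 to 0.133). The median was -0.18 without untreated colitis mouse 5 and -0.06 without mouse 6. Galnt12 (-0.64 ± 0.11), Spink4 (-0.84 ± 0.19) and Spdef (-0.55 ± 0.13) were among the 4 of 15 members that fell, 11 not passing and 4 down adjusted over the list alone.

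Smooth muscle, posterior Hox, adipocyte, colonocyte and xenobiotic metabolism lists rose under cyclosporine, and matrix genes fell. Smooth muscle markers rose as a list (median 0.45, adjusted p = 1.65e-08, adjusted p = 0.331 with an estimated correlation). Casq2 (1.14 ± 0.16), Kcnmb1 (0.62 ± 0.12) and Pgm5 (0.85 ± 0.18) were among the 12 of 14 members that rose, 2 not passing and 13 up adjusted over the list alone. Posterior Hox genes rose as a list (median 0.45, adjusted p = 0.00198, adjusted p = 0.331 with an estimated correlation). Hoxd11 (1.31 ± 0.27) and Hoxd10 (0.87 ± 0.20) were among the 4 of 8 members that rose, 4 not passing and 5 up adjusted over the list alone. Adipocyte markers rose as a list (median 0.62, adjusted p = 0.000200, adjusted p = 0.331 with an estimated correlation). Of 10 members 2 rose, 8 not passing and 6 up adjusted over the list alone. Thrsp (1.54 ± 0.31) rose. Cyclosporine mouse 9 had a low adipocyte mean (7.11). Colonocyte markers rose as a list (median 0.21, adjusted p = 0.00965, adjusted p = 0.331 with an estimated correlation). The median was 0.32 without cyclosporine mouse 9. Of 18 members 7 rose and 1 fell, 10 not passing and 7 up and 1 down adjusted over the list alone. Slc37a2 (2.23 ± 0.33), Slc26a3 (0.99 ± 0.16) and Car1 (0.66 ± 0.12) rose while Guca2b (-0.48 ± 0.10) fell. Xenobiotic metabolism genes rose as a list (median 0.26, adjusted p = 0.000102, adjusted p = 0.269 with an estimated correlation). Of 19 members 6 rose and 1 fell, 12 not passing and 10 up and 1 down adjusted over the list alone. Gstm1 (0.91 ± 0.12), Ces1f (1.33 ± 0.20) and Sult1a1 (1.52 ± 0.23) rose. Matrix and wound repair genes fell as a list (median -0.61, adjusted p = 0.000200, adjusted p = 0.395 with an estimated correlation). The median was -0.36 without untreated colitis mouse 5 and -0.31 without mouse 7. Of 17 members 1 rose and 4 fell, 12 not passing and 1 up and 8 down adjusted over the list alone. Col4a1 (-0.64 ± 0.13) and Col1a1 (-0.61 ± 0.15) fell while Postn (0.63 ± 0.11) rose. Not called were enteric neuron and glia markers (median 0.09, adjusted p = 0.0770), endothelial markers (median 0.06, adjusted p = 0.158) and fatty acid oxidation genes (median 0.09, adjusted p = 0.0766). Neuron and glia markers were called up without cyclosporine mouse 4 (median 0.16, adjusted p = 0.000820), and endothelial markers without untreated colitis mouse 5 or 7 (median 0.15 to 0.16, adjusted p = 0.00875 to 0.0271). Fatty acid oxidation genes were called up without untreated colitis mouse 6 or 7 or cyclosporine mouse 10 (median 0.11 to 0.12, adjusted p = 0.0126 to 0.0437).

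Interferon and macrophage genes were higher in cyclosporine colitis than in untreated healthy mice. Effects of DSS and cyclosporine cannot be told apart here. The interferon genes Ddx60 (1.70 ± 0.31), Oas2 (1.63 ± 0.28) and Oasl2 (1.52 ± 0.31), the macrophage gene Gpnmb (1.77 ± 0.23) and the neutrophil surface gene Cd177 (1.33 ± 0.21) were higher. Plet1 (1.38 ± 0.35) was higher too, a call lost without untreated healthy mouse 2, 6 or 7 or cyclosporine mouse 4, 9 or 10 (adjusted p = 0.0505 to 0.0741). The ion transport regulator Fxyd4 (-1.59 ± 0.29), the phosphate transporter Slc20a1 (-1.08 ± 0.23) and the sialyltransferase gene St8sia5 (-1.11 ± 0.24) were lower. In all 442 genes were higher and 566 lower, 39 and 4 of them by at least 2-fold. Leaving out each array in turn, 25 of 52 genes tested lost their call. The count of 1008 was 371 without untreated healthy mouse 2, 622 without mouse 6 and 427 without mouse 7. It was 456 without cyclosporine mouse 4, 553 without mouse 10 and 539 in a fit of these 8 arrays alone.

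Of 28 lists 11 were called between cyclosporine colitis and untreated healthy mice, 8 up and 3 down. Type I interferon genes were higher as a list (median 0.44, adjusted p = 2.05e-08, adjusted p = 0.398 with an estimated correlation). Of 18 members 6 were higher, 12 not passing and 9 up adjusted over the list alone. Macrophage markers were higher as a list (median 0.45, adjusted p = 5.91e-08, adjusted p = 0.398 with an estimated correlation). Ms4a7 (1.08 ± 0.12) and Mpeg1 (0.95 ± 0.19) were among the 4 of 17 members that were higher, 13 not passing and 9 up adjusted over the list alone. Interferon gamma and MHC class II genes were higher as a list (median 0.57, adjusted p = 3.36e-08, adjusted p = 0.398 with an estimated correlation). Of 17 members 3 were higher, 14 not passing and 12 up adjusted over the list alone. Gbp3 (1.07 ± 0.23) was higher. Epithelial antimicrobial genes were higher as a list (median 0.58, adjusted p = 0.00238, adjusted p = 0.398 with an estimated correlation). The median was 0.31 without cyclosporine mouse 4. Of 16 members 1 was higher, 15 not passing and 1 up adjusted over the list alone. Duox2 (0.90 ± 0.15) was higher. T cell markers were higher as a list (median 0.19, adjusted p = 0.00238, adjusted p = 0.551 with an estimated correlation). The median was 0.13 without untreated healthy mouse 7. Of 13 members 2 were higher, 11 not passing and 2 up adjusted over the list alone. B cell and plasma cell markers were higher as a list (median 0.51, adjusted p = 0.00208, adjusted p = 0.485 with an estimated correlation). Of 15 members 0 passed over all genes and 0 adjusted over the list alone.

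Vascular and matrix lists were higher, and metabolic lists lower, in the same comparison. Endothelial markers were higher as a list (median 0.28, adjusted p = 6.83e-05, adjusted p = 0.438 with an estimated correlation). Of 14 members 2 were higher, 12 not passing and 3 up adjusted over the list alone. Matrix and wound repair genes were higher as a list (median 0.16, adjusted p = 0.00600, adjusted p = 0.628 with an estimated correlation). Of 17 members 0 passed over all genes and 0 adjusted over the list alone. Fatty acid oxidation genes were lower as a list (median -0.24, adjusted p = 0.000793, adjusted p = 0.398 with an estimated correlation). Ech1 (-0.49 ± 0.08) and Acadvl (-0.38 ± 0.06) were among the 4 of 16 members that were lower, 12 not passing and 8 down adjusted over the list alone. Xenobiotic metabolism genes were lower as a list (median -0.28, adjusted p = 0.00222, adjusted p = 0.398 with an estimated correlation). Nr1i3 (-0.51 ± 0.09) and Gstt1 (-0.41 ± 0.08) were among the 4 of 19 members that were lower, 15 not passing and 9 down adjusted over the list alone. Colonocyte markers were lower as a list (median -0.20, adjusted p = 0.0233, adjusted p = 0.438 with an estimated correlation), a call lost without untreated healthy mouse 2 (adjusted p = 0.0706). The median was -0.30 without untreated healthy mouse 6. Of 18 members 3 were lower, 15 not passing and 6 down adjusted over the list alone. Car1 (-0.61 ± 0.12) was lower. Not called were neutrophil markers (median 0.04, adjusted p = 0.527), acute inflammatory cytokines (median 0.12, adjusted p = 0.279) and smooth muscle markers (median -0.14, adjusted p = 0.134). Smooth muscle markers were called down without cyclosporine mouse 7 or 9 (median -0.21 to -0.20, adjusted p = 0.0141 to 0.0303).

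Among mice given the probiotic, inflammatory genes rose and colonocyte genes fell in colitis. This comparison with probiotic healthy mice asks how DSS injury looks under that treatment. Clca4b (5.73 ± 0.73), Plet1 (4.91 ± 0.35), Il1b (4.00 ± 0.71) and Nos2 (3.81 ± 0.43) rose, beside the chemokine gene Cxcl9 (3.64 ± 0.56) and the myeloid gene Sirpb1c (3.33 ± 0.49). The largest falls were those of Fxyd4 (-3.65 ± 0.29), Mptx1 (-3.56 ± 0.52) and Slc37a2 (-3.42 ± 0.33). The cytochrome P450 genes Cyp2c55 (-3.16 ± 0.46) and Cyp2c69 (-3.15 ± 0.51) and the magnesium channel gene Trpm6 (-2.55 ± 0.25) fell too. In all 2280 genes rose and 2689 fell, 575 and 163 of them by at least 2-fold. Of 28 lists 26 were called, 17 up and 9 down. Macrophage markers rose as a list (median 1.21, adjusted p = 1.43e-12, adjusted p = 0.0944 with an estimated correlation). Of 17 members 15 rose, 2 not passing and 15 up adjusted over the list alone. Interferon gamma and MHC class II genes rose as a list (median 1.58, adjusted p = 4.52e-16, adjusted p = 0.0944 with an estimated correlation). Of 17 members 17 rose, 0 not passing and 17 up adjusted over the list alone.

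No single gene passed for a difference between the probiotic change in colitis and that in healthy colon, the question of the interaction. Of 28 lists 8 were called by camera, all up, but 0 with an estimated correlation and 0 by fry. In limma 0 genes passed, with 1446 at an unadjusted p under 0.05 and a smallest adjusted p of 0.185. The smallest p upward were those of the lymphocyte regulator Prdm1 (1.05 ± 0.18, adjusted p = 0.185), the macrophage gene Aif1 (0.97 ± 0.17, adjusted p = 0.185) and the purine receptor P2rx7 (0.58 ± 0.11, adjusted p = 0.193). Downward they were those of Rflnb (-0.50 ± 0.10, adjusted p = 0.193), St3gal3 (-0.56 ± 0.11, adjusted p = 0.258) and Mex3c (-0.42 ± 0.09, adjusted p = 0.299). Not called were colonocyte markers (median -0.22, adjusted p = 0.0707), which were called down without untreated healthy mouse 2 or untreated colitis mouse 5 or probiotic healthy mouse 5 or probiotic colitis mouse 8 (median -0.35 to -0.28, adjusted p = 0.00154 to 0.0373). Macrophage markers had the largest difference (median 0.59, adjusted p = 7.08e-09, adjusted p = 0.741 with an estimated correlation). Of 17 members 0 passed over all genes and 2 up adjusted over the list alone. T cell markers were called too (median 0.30, adjusted p = 0.000163, adjusted p = 0.741 with an estimated correlation). The median was 0.59 without untreated colitis mouse 5. Of 13 members 0 passed over all genes and 1 up adjusted over the list alone. Without probiotic colitis mouse 8 there were 45 genes, Aif1 (adjusted p = 0.00944), Prdm1 (adjusted p = 0.0330), P2rx7 (adjusted p = 0.0363) and Rflnb (adjusted p = 0.0434) among them, and 14 lists, and without untreated healthy mouse 2 there were 13 lists. Without the 3 arrays that stand apart 13 genes passed.

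Immune genes were lower and colonocyte genes higher under cyclosporine than under the probiotic. This comparison asks how the treatments differ in colitis. The neutrophil genes Retnlg (-4.24 ± 1.02) and S100a8 (-3.45 ± 0.82) were lower. So were Plet1 (-4.04 ± 0.35), Saa3 (-3.98 ± 0.97) and Il1b (-3.72 ± 0.71). The cytochrome P450 genes Cyp2c69 (3.68 ± 0.51) and Cyp2c55 (3.20 ± 0.46), the pentraxin Mptx1 (2.88 ± 0.52) and the channel gene Trpm6 (2.26 ± 0.25) were higher. In all 1884 genes were higher and 2006 lower, 107 and 396 of them by at least 2-fold. Of 28 lists 24 were called, 8 up and 16 down. Handling genes were lower too (median -0.32, adjusted p = 0.00348), a call lost without probiotic colitis mouse 8 (adjusted p = 0.153). Adipocyte markers were higher (median 0.38, adjusted p = 0.00906). Macrophage markers were lower as a list (median -1.01, adjusted p = 1.48e-10, adjusted p = 0.126 with an estimated correlation). Aif1 (-0.98 ± 0.12) and Csf1r (-1.34 ± 0.20) were among the 13 of 17 members that were lower, 4 not passing and 14 down adjusted over the list alone. Colonocyte markers were higher as a list (median 0.68, adjusted p = 7.80e-06, adjusted p = 0.0993 with an estimated correlation). Slc26a3 (1.55 ± 0.16), Car1 (1.14 ± 0.12) and Aqp8 (1.39 ± 0.20) were among the 8 of 18 members that were higher, 10 not passing and 8 up adjusted over the list alone.

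A colitis score summed up each array as the mean of 283 genes higher minus the mean of 52 genes lower in the 3 colitis groups together than in the 2 healthy groups, a choice of genes that is orthogonal to differences among the colitis groups. It averaged -2.85 ± 0.16 (SD, n = 4) in untreated healthy mice, -2.58 ± 0.15 in probiotic healthy mice, 0.49 ± 0.67 in untreated colitis, 1.41 ± 0.91 in probiotic colitis and -1.63 ± 0.30 in cyclosporine colitis. Cyclosporine colitis differed from untreated colitis by -2.12 (exact two-sided permutation p = 0.0286, the smallest that 4 against 4 allows, adjusted p = 0.0571 over the 4 comparisons that the choice of genes does not favour), with all 4 cyclosporine mice below all 4 untreated mice. That difference is -63.4% of the shift from untreated healthy to untreated colitis, a shift for which the genes were chosen. Without cyclosporine mouse 7 its exact permutation p was 0.0571. Probiotic colitis differed from untreated colitis by 0.93 (exact permutation p = 0.200, adjusted p = 0.200). Of the probiotic mice 3, at 1.83 to 1.89, lay above all untreated mice, whose highest was 1.14, and mouse 8 lay at 0.0520. Without mouse 8 the difference was 1.38 (exact permutation p = 0.0571), and without it and untreated colitis mouse 6, chosen after seeing the data, 1.07 (exact permutation p = 0.1). With no minimum fold for the genes the probiotic and cyclosporine differences were 0.22 and -0.49 (exact permutation p = 0.200 and 0.0286), and with lists fixed in advance 0.40 and -1.17 (exact permutation p = 0.486 and 0.0286). Cyclosporine differed from probiotic colitis by -3.05 (exact permutation p = 0.0286, adjusted p = 0.0571), and the healthy groups differed by 0.28 (exact permutation p = 0.0571, adjusted p = 0.0762). So no difference in the score passed after adjustment. Cyclosporine colitis lay 1.22 above untreated healthy, which was not tested because the genes were chosen for such a difference.

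**Figure D2:**
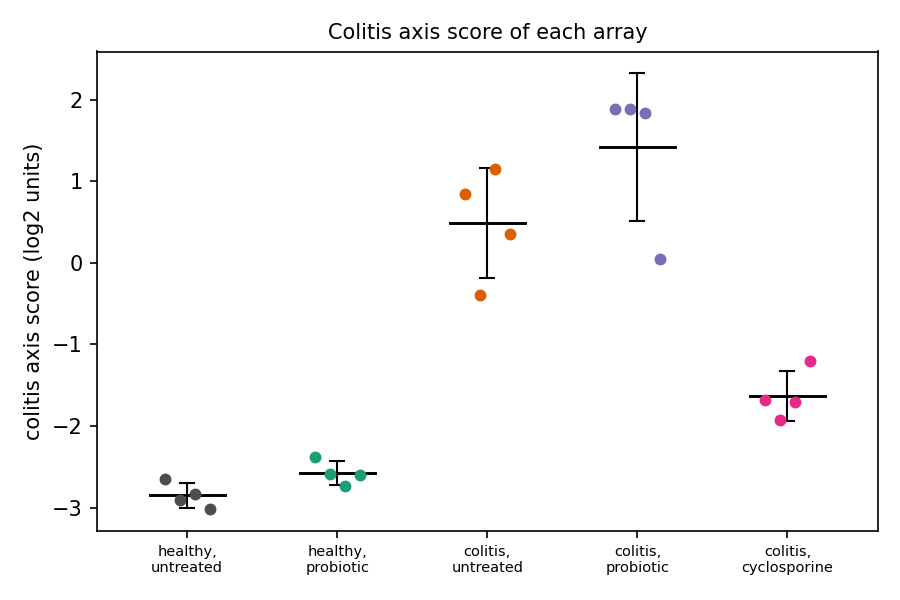
Colitis score (log2 units) of each of the 20 arrays (points) with the group mean and SD (bars, n = 4), by group. The cyclosporine mean of -1.63 lies between -2.85 in untreated healthy and 0.49 in untreated colitis, and the probiotic colitis mean is 1.41.

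Across genes, which are not independent replicates, no correlation between comparisons lay beyond the range of 100 simulations with no group effect. The colitis and cyclosporine changes, which share the untreated colitis arrays, had a Pearson correlation of -0.82, against a mean of -0.39 (-0.89 to 0.50) simulated. With these split 2 and 2, none being shared, it was -0.64 (-0.75 to -0.53). Their covariance was -0.089, against -0.0067 simulated and -0.077 split. The colitis and probiotic changes in colitis had a correlation of 0.299, near the top of -0.93 to 0.303 simulated (mean -0.48). Split it was 0.34 (0.05 to 0.56). The probiotic and cyclosporine changes in colitis had a correlation of -0.09, against 0.49 (-0.32 to 0.90) simulated and -0.19 (-0.46 to 0.14) split. It was 0.03 without untreated colitis mouse 5 and -0.34 over score genes alone. No simulated range is given for split values or covariances. The probiotic changes in healthy mice and colitis, sharing no array, had a correlation of 0.39 (-0.77 to 0.72 simulated).

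**Figure D3:**
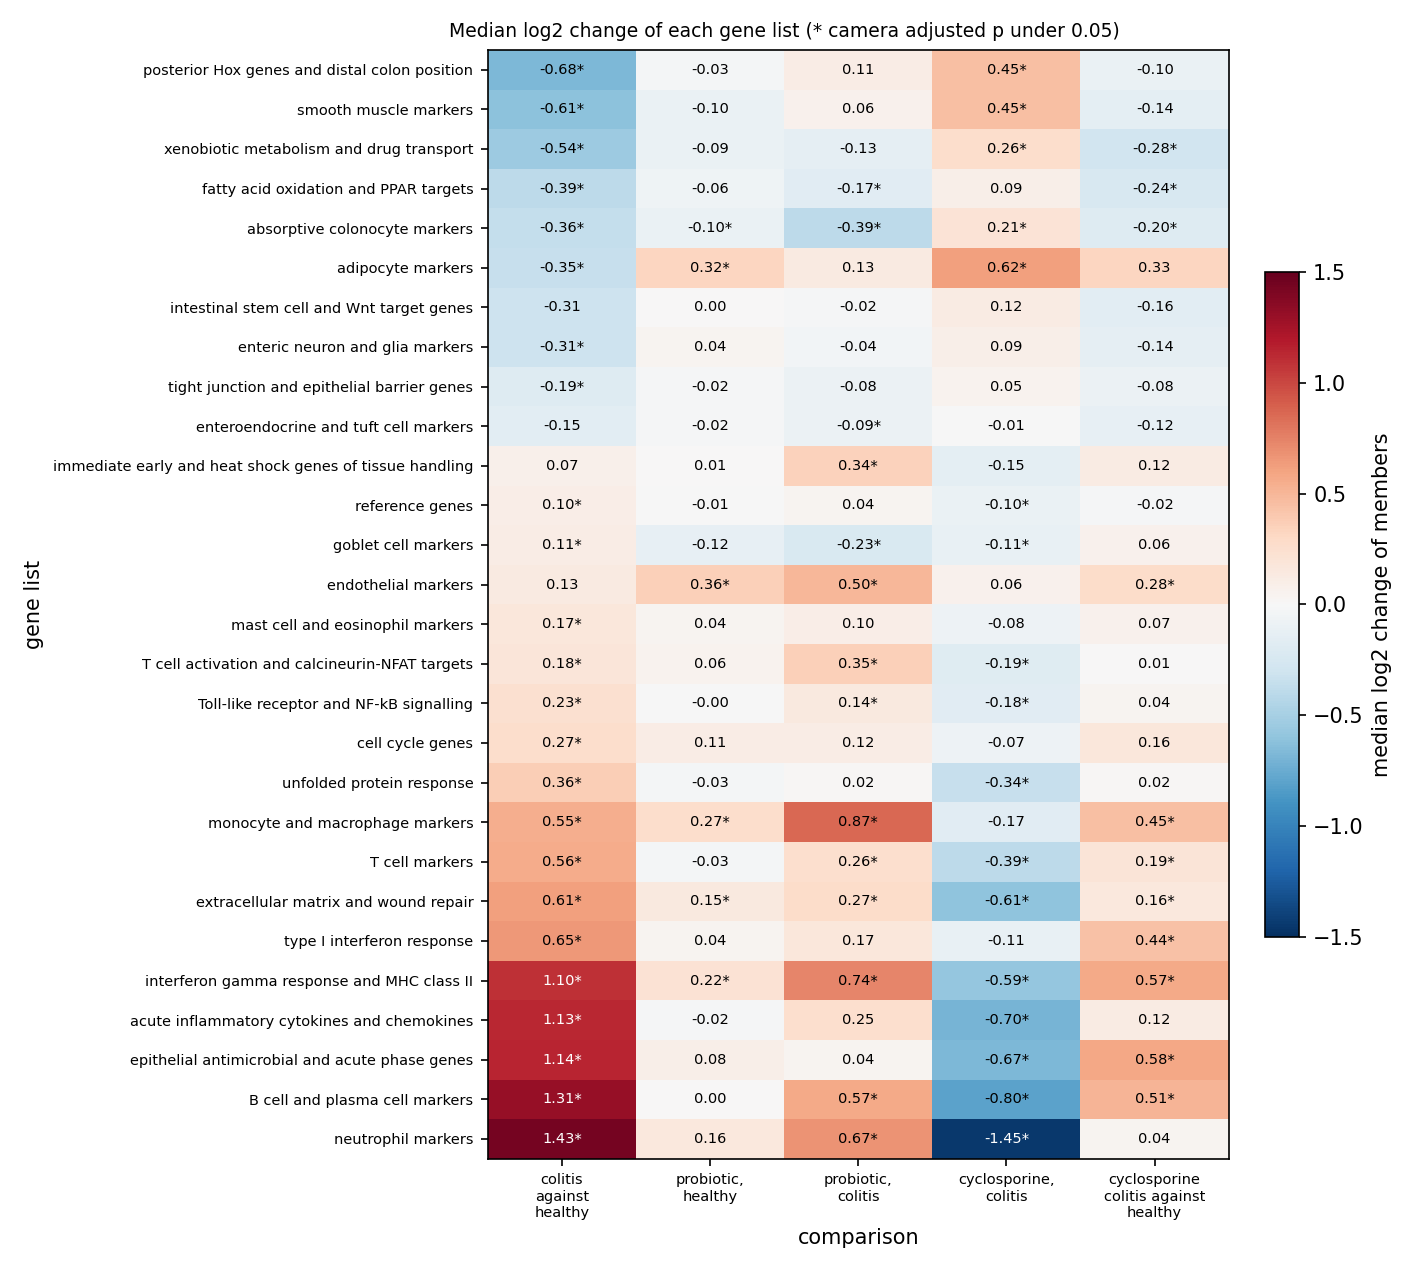
Median log2 change (colour) of 28 gene lists (vertical axis) in 5 comparisons (horizontal axis), with an asterisk where the list was called by camera at the preset correlation. Smooth muscle markers had a median of -0.61 in colitis against healthy and of 0.45 in cyclosporine against untreated colitis.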

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

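Of the tests weighed here, those of epithelial share, of a batch of treated arrays and of dilution, and lists refitted without 1 or 3 arrays or after quantile normalization, were chosen only after the result was seen. The list of anterior Hox genes was added after the fall of posterior ones was seen, but before its own values were. Single arrays far from the other 3 of their group were looked for in 175 groups of 4 values, and 14 were found where chance gives about 1 in 20, or 8.75. Of these, 8 were probiotic colitis mouse 8. Its colitis score was 0.0520 against 1.83 to 1.89 in the other 3 mice. Its means were low for macrophage markers (8.57 against 9.14 to 9.23), type I interferon genes (7.41 against 8.13 to 8.26), interferon gamma and MHC class II genes (8.59 against 9.77 to 9.92) and Toll-like receptor and NF-kB genes (8.18 against 8.45 to 8.51), and high for tight junction genes (9.15 against 8.99 or slightly more) and xenobiotic metabolism genes (7.96 against 7.60 to 7.66). Its Oas2 was 7.84 against 8.80 to 8.87. Untreated healthy mouse 2 had a high goblet cell mean (11.1 against 10.87 to 10.89) and a low endothelial mean (7.21 against 7.46 to 7.49). The mast cell and eosinophil mean of untreated healthy mouse 6 was 5.50 against 5.59 to 5.60, and the stem cell and Wnt mean of untreated colitis mouse 10 was 8.06 against 7.95 in the other 3. Slc37a2 of untreated colitis mouse 7 was 7.42 against 8.37 to 8.55, and the adipocyte mean of cyclosporine mouse 9 was 7.11 against 8.13 to 8.32.

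The probiotic change differed between colitis and healthy mice for 8 lists by the interaction test, all with a higher value in colitis. Without the 3 arrays that stand apart the calls of B cell and plasma cell markers (median 0.19, adjusted p = 0.227) and smooth muscle markers (median 0.07, adjusted p = 0.227) were lost, type I interferon genes (median 0.18, adjusted p = 0.0363) and matrix genes (median 0.13, adjusted p = 0.0410) were called up, and lists with a lower value in colitis were called: colonocyte markers (median -0.44, adjusted p = 0.000146), goblet cell markers (median -0.18, adjusted p = 0.0103), enteroendocrine and tuft cell markers (median -0.17, adjusted p = 0.00969) and fatty acid oxidation genes (median -0.15, adjusted p = 0.0130). Colonocyte markers were also called down after quantile normalization (median -0.26, adjusted p = 0.0391). The median differences were 0.45 for neutrophil markers (adjusted p = 0.0273), 0.59 for macrophage markers (adjusted p = 7.08e-09), 0.30 for T cell markers (adjusted p = 0.000163), 0.32 for T cell activation targets (adjusted p = 0.000528), 0.50 for B cell and plasma cell markers (adjusted p = 0.00201), 0.48 for interferon gamma and MHC class II genes (adjusted p = 9.11e-06), 0.15 for Toll-like receptor and NF-kB genes (adjusted p = 0.00201) and 0.17 for smooth muscle markers (adjusted p = 0.0144). With an estimated correlation none was called, the adjusted p being 0.783 for neutrophil and smooth muscle markers and 0.741 for the others. The neutrophil call was lost without untreated colitis mouse 5 or 6 or probiotic healthy mouse 6 or 7 or probiotic colitis mouse 3 or 7 (adjusted p = 0.0625 to 0.442), the B cell call without untreated colitis mouse 6 (adjusted p = 0.0833) and the smooth muscle call without untreated colitis mouse 7 or probiotic healthy mouse 7 or probiotic colitis mouse 8 (adjusted p = 0.0540 to 0.224). Medians moved by over 1.5 times for neutrophil markers (0.13 to 1.15 without untreated colitis mouse 6 or 7 or probiotic colitis mouse 7 or 8), T cell markers (0.59 without untreated colitis mouse 5), T cell activation targets (0.18 without untreated colitis mouse 6), B cell markers (0.79 without untreated colitis mouse 5 and 0.29 without mouse 6), interferon gamma genes (0.76 without probiotic colitis mouse 8), Toll-like receptor genes (0.25 without probiotic colitis mouse 8) and smooth muscle markers (0.08 to 0.26 without untreated colitis mouse 7 or probiotic colitis mouse 7 or 8). Probe sets with no or several gene names, which no comparison used, also differed, 505 of 3887 between untreated colitis and untreated healthy mice (243 up, 262 down), against 153 between cyclosporine and untreated colitis, 10 between probiotic and untreated colitis and 0 between the healthy groups.

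More genes differed between probiotic and untreated colitis in the fit of 20 arrays (468) than in the fit of those 8 (0 in limma). All 468 had an unadjusted p under 0.05 in the fit of 8. Their folds come from the same 8 arrays in both fits, so the equal sign is fixed and that p is no separate support. Stronger colitis in the probiotic arrays cannot cause this gap in counts but may account for part of the folds. With the colitis score as covariate 73.5% of the median fold was left (51.6% to 84.1% on leaving out 1 array, jackknife SE 23.7). That is not beyond its spread from the bound of 50%. The median log2 fold then fell from 0.53 to 0.39 and 38 genes were called, 34 of the 468 among them, while all 468 kept their sign and 467 an unadjusted p under 0.05. For the gap in counts, a spread shared with less variable healthy arrays stays open. The residual variance of the colitis arrays was 3.02 times that of the healthy arrays over the called genes. It was 1.18 times over all genes, and the prediction had not named the gene set. A probiotic shift shared with healthy mice was 29.1% of the fold in colitis (26.4% to 32.6% on leaving out 1 array, 404 of 468 genes of the same sign), between the bounds of 25% and 50%, so it is neither excluded nor borne out.

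Endothelial markers were higher in both probiotic groups than in their untreated groups, calls lost with an estimated correlation (adjusted p = 0.603 and 0.224), and also in cyclosporine colitis against untreated healthy (median 0.28, adjusted p = 6.83e-05, and 0.438 with an estimated correlation), so higher values were not limited to probiotic groups. A lower share of epithelium could raise other layers alike. In healthy mice the endothelial median exceeded the smooth muscle median by 0.46 (jackknife SE 0.067), which argues only against an equal rise. Treated arrays handled as a batch of their own are neither shown nor excluded: outside the genes that differ between colitis and healthy arrays, the healthy probiotic and the cyclosporine changes, which share no array, had a correlation of 0.288 across genes, against 0.0371 over all genes. That lies within the -0.65 to 0.57 of 100 simulations with no group effect (44 at least as large in size), so chance alone gives such a value. An effect of treatment on vessels may also apply and was not tested apart.

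Smooth muscle, enteric neuron and posterior Hox genes were lower in untreated colitis than in healthy colon. Uniform dilution by other cells would lower every resident layer alike. The endothelial median exceeded the smooth muscle median by 0.74 (jackknife SE 0.22), which argues against that alone. Tissue from a more proximal position could lower posterior Hox genes, and would raise anterior ones, whose median change was -0.00525 (jackknife SE 0.057) over 12 genes with 0 up and 0 down. That value met neither bound, so position stays open. So do uneven dilution and an effect of DSS on these layers, not tested apart.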

How the results depend on the processing

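Leaving out the 3 arrays that stand apart, a score without untreated colitis mouse 6 and probiotic colitis mouse 8, and lists refitted without each array or after quantile normalization were chosen after seeing the data. Gene counts stayed within 1.5 times their value with no filter, a stricter filter, either scaling, eBayes with trend and robust, and a mean of probe sets. Array weights gave 1682 genes for the probiotic in colitis and 5 for the interaction. Animal number as a block gave 219 for the probiotic in colitis, 25 for cyclosporine against untreated healthy, 2100 for cyclosporine against probiotic and 1 for the interaction, with 15 interaction lists. Of the 20 same-numbered pairs of arrays 5 had residuals correlated above 0.1 (-0.19 to 0.43), and over the 8 pairs of groups that share 2 or more numbers an array matched best with its own number in 12 of 36 checks, which does not show pairing by number. Only untreated and probiotic colitis matched throughout (mouse 5 r = 0.25, mouse 7 r = 0.43), and 2 pairs are too few to settle it for them. The compared groups fitted alone gave 19 genes for the probiotic in healthy mice, 0 for the probiotic in colitis, 1119 for cyclosporine in colitis and 539 for cyclosporine against untreated healthy. Without the 3 arrays 13 interaction genes passed. Leaving out 1 array gave 71 to 1223 genes for the probiotic in colitis, 1353 to 2447 for cyclosporine in colitis, 371 to 1050 for cyclosporine against untreated healthy and 0 to 45 for the interaction, 3 to 6 lists for the probiotic in healthy mice and 6 to 14 for the interaction. The score difference under cyclosporine was -2.35 to -1.91, and the correlation of probiotic and cyclosporine changes -0.26 to 0.03, reversed (0.0279) without untreated colitis mouse 5 and -0.34 over score genes. With cyclosporine mouse 7 left out the exact p of the score difference was 0.0571, which is above the smallest p possible with 3 against 4.

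With an estimated correlation 1 list was called for colitis and 0 in any other comparison. With fry 0 were called for the probiotic in healthy mice, 7 for it in colitis, 11 for cyclosporine in colitis, 7 for cyclosporine against untreated healthy and 0 for the interaction. No named gene and no called list changed direction under any alternative. Lists not called were called in 6 cases with no filter, 3 after centring, 1 after quantile normalization, 21 with the block, 20 without the 3 arrays, 6 with fry and 39 on leaving out 1 array or another. Of 130 list calls, 1 was lost with no filter, 1 after centring, 3 after quantile normalization, 11 with the block, 11 without the 3 arrays, 40 with fry and 129 with an estimated correlation, and 24 were lost on leaving out 1 array or another. Of 570 calls of named genes and list members 127 were lost on leaving out 1 array or another. Of 705 calls and values of named genes and list members, 34 lost their call with no filter, 14 and 4 after centring and quantile normalization, 19 with trend and robust, 10 with array weights, 123 with the block, 106 fitted alone and 30 without the 3 arrays. Calls gained were 41 with array weights, 3 and 5 after centring and quantile normalization, 1 with trend and robust, 10 with the stricter filter, 8 with the block, 10 fitted alone and 28 without the 3 arrays. Genes removed by the stricter filter or by the filter after quantile normalization have no value there.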

Other observations

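Apart from quantile normalization and left-out arrays for the lists, chosen after the data were seen, the tests here were fixed with the design. Some genes often used as references for expression changed in colitis. As a list they rose in untreated colitis (median 0.10, adjusted p = 0.00958, adjusted p = 0.186 with an estimated correlation), the median being 0.06 to 0.16 without untreated healthy mouse 2 or 7 or untreated colitis mouse 6 or 7. Of 11 members 4 rose, 7 not passing and 4 up adjusted over the list alone. B2m (0.57 ± 0.08), Gusb (0.70 ± 0.11) and Hprt (0.42 ± 0.10) rose, B2m being an MHC class I subunit and Gusb a lysosomal enzyme. Under cyclosporine the list fell against untreated colitis (median -0.10, adjusted p = 0.00965, adjusted p = 0.331 with an estimated correlation), the median being -0.15 without untreated colitis mouse 6 and -0.15 without cyclosporine mouse 4. Of 11 members 3 fell, 8 not passing and 4 down adjusted over the list alone. Gusb (-0.72 ± 0.11) and Pgk1 (-0.44 ± 0.09) fell. In healthy mice given the probiotic no reference gene passed (median -0.01, adjusted p = 0.913). Directions of these lists were the same under both scalings. Immediate early and heat shock genes, which respond to handling, were not called in untreated colitis (median 0.07, adjusted p = 0.118). Of 16 members 1 rose, 15 not passing and 0 adjusted over the list alone.

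Other splits of the same arrays into groups of 4 and 4 showed where the real split stood out. The real split gave more genes than the 34 others for colitis against healthy (4361, highest other 1, 1 of 35 splits as large), cyclosporine against untreated colitis (2202, highest other 383, 1 of 35), colitis under the probiotic (4969, highest other 5, 1 of 35), cyclosporine against untreated healthy (1008, highest other 0, 1 of 35) and cyclosporine against probiotic (3890, highest other 2085, 1 of 35), so chance is excluded for these 5. For the probiotic in colitis the real split did not stand out, as 3 of 35 splits gave as many genes (468, highest other 1387). In healthy mice and for the interaction 0 genes were called, so every split gives as many by construction (35 of 35, highest other 3, and 100 of 100, highest other 324) and the splits say nothing on chance. The split with 1387 genes set untreated colitis mouse 5 with probiotic colitis mice 3, 5 and 7 against the rest, and the one with 792 did the same with untreated colitis mouse 7. The split with 2085 set cyclosporine mouse 10 with probiotic colitis mice 3, 5 and 7. All 3 place probiotic colitis mouse 8 with the other group, a structure of these samples that the labels do not explain.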
